A study of Mus musculus with 18 samples.

How the data were processed

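The series holds 17 RNA sequencing libraries from mice at postnatal day 28, bred as reciprocal hybrids of the strains B6 and CAST. The labels give 4 tissues (visual cortex, motor cortex, retina and suprachiasmatic nucleus, SCN), normal or dark rearing, and 1 of 2 crosses: F1i, with a CAST mother and a B6 father, or F1r, with a B6 mother and a CAST father. Total RNA was made into strand-specific libraries. A tail DNA sample is not analysed here. Tissue, rearing and cross were read from the sample titles and fixed before the data were examined, as were the comparisons, the tests, the gene lists, the rule for named genes and most of the other settings tried.

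The deposited gene tables hold FPKM values, fragments scaled by transcript length and library size, that the authors computed. TopHat, Cufflinks and the genome build GRCm38 are named in the submitters' processing notes, and their versions, the annotation release and the filters are not given in the sources used here. The deposited allele tables hold, per the file headers, counts of reads that hit 1 transcript, or 1 parental copy of it, and no other. The columns have the form of MMSEQ output, and the program, its version and the strain variants behind it are not given in the sources used here. Coordinates are those of the gene tables, counted from 1. The deposited isoform tables, and sheets that copy or are derived from these tables, are not used here.

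The gene tables of 5 libraries (motor cortex F1r, both retina and both SCN libraries, all dark-reared) list 43496 genes and those of the other 12 list 37168. They are called the newer and the older gene set here. Of 44614 genes in any table, 35971 were in every table, and 29623 of these had the same position and transcripts in both sets. Values of a gene listed more than once in a table were summed (20 such genes in the older set and 59 in the newer), and 2 unreadable lines of an allele table were left out. A symbol was found in the reference table for 42276 genes. Genes with a second copy on an alternate contig of the newer set were marked, as were genes with fewer than 10 unique reads in every library.

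For expression, each library was divided by its median ratio to the geometric mean of all libraries, over genes with an FPKM of at least 1 in every library. These factors ran from 0.488 (dark-reared retina, F1i) to 1.30. Genes with an FPKM of at least 1 in at least 2 libraries (15706) were analysed as log2(FPKM + 1) with limma 3.58.1, with a mean for each of the 8 groups and the cross as a covariate, and empirical Bayes moderation with a trend (10.5 degrees of freedom with the prior). Contrasts compared dark with normal rearing in each tissue and on average, the dark effect between visual and motor cortex and between retina and SCN, visual with motor cortex, retina with SCN, and the crosses. Log2 values compare dark minus normal, visual minus motor, retina minus SCN, or F1r minus F1i. P-values are two-sided and Benjamini-Hochberg adjusted over all genes tested, with a threshold of 0.05. For the 27 gene lists, camera was run with a preset correlation of 0.01 and, beside it, with a correlation estimated from the data. Counts "adjusted over the list alone" apply the correction to the members only.

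For allele comparisons, maternal and paternal reads were summed by gene. Autosomal genes were kept with at least 10 allele reads in at least 10 libraries, among them at least 1 library of each cross in every tissue (6602). They entered an edgeR 4.0.16 quasi-likelihood fit of both allele columns of each library, with a term for each library, a maternal effect for each of the 8 groups and a B6 effect for each of the 4 tissues. Library sizes were set equal within a library, 5 residual degrees of freedom remained and the common dispersion was 0.0655. Positive values mean a fitted excess of maternal, or of B6, reads. Reciprocal crosses separate the parental from the strain effect.

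Named genes followed 1 rule. Among genes past the threshold whose groups do not overlap (past the threshold only, for interactions and averages), the 10 highest and the 10 lowest log2 values with a protein-coding or lincRNA symbol are named, leaving out predicted genes and pseudogenes, plus up to 4 passing members of each list by smallest p. For alleles, every tested gene of the list of known imprinted genes is named, plus up to 10 others by smallest adjusted p.

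Both methods were tested on data simulated from the levels of these genes, with changes planted in 200 of the better expressed ones. Genes were drawn independently of each other, allele reads with a fixed dispersion, and no date effect was simulated. With log2 changes of -2, -1, 1 and 2 in 50 genes each, limma called 46, 32, 29 and 45 in visual cortex, with 9 unchanged genes called there and 0 in motor cortex. The parental effect was called in 49, 48, 49 and 50 genes, with 16 unchanged genes called, and a parental effect that differed by rearing in 48, 24, 27 and 50, with 5 unchanged genes called. A change of 1 planted in the clock list gave a camera adjusted p of 2.20e-26, and 0 of the 27 lists were called without it. As the simulated genes were not correlated, this cannot show how the list test behaves with correlated genes.

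Unique reads per library ran from 4003792 to 11169087 and allele reads from 548644 to 3331266. Mapped fragments, given in the tables with the older set alone, ran from 13172472 to 26000820. Reads without a gene were at most 0.279% of a library. Intervals and spreads of reads cover counting error only, since the reads carry no molecular identifiers. Imprinted genes were checked against the cross label in every library: each had 5 to 8 such genes with at least 20 reads, all read mostly from the parent that expresses them, the lowest share being 92.2% (95% Wilson interval 90.5% to 93.7%) for Impact in dark-reared visual cortex, replicate 3. No paired analysis was run: replicate numbers name no animal, and libraries that share a sequencing label, such as retina and SCN of 1 cross and rearing, were not treated as pairs.

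Settings tried beside the main ones, chosen before the data were examined, changed the pseudocount, the filter, the scaling, the cross term, a random block for the date label, the libraries fitted, the averaging of the 2 dark-reared visual cortex F1r libraries, the test (edgeR on unique reads, DESeq2 1.42.0, limma with precision weights), the allele normalisation, the read minimum and X-linked genes, and left out each library in turn. Settings chosen after seeing the data used genes with 1 model in both gene sets, genes with no second copy, the mt-Rnr2 share as a covariate, no chromosome 19, an extra B6 effect for the newer set, and no normally reared F1r retina and SCN libraries. Computations used R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Results of some of the named genes are not reported here.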

Results

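Gene expression and allele-specific reads were measured in visual cortex, motor cortex, retina and SCN, the hypothalamic nucleus that holds the circadian clock, of B6 and CAST hybrid mice at postnatal day 28. Mice were reared normally or in darkness, and the series title frames the question as which genes and which imprinted alleles depend on experience in the developing visual system. Visual cortex had 2 normally reared and 3 dark-reared libraries, and each of the other tissues had 2 of each rearing. Each group held 1 library of the F1i cross (CAST mother) and 1 of the F1r cross (B6 mother), and dark-reared visual cortex had a second F1r library. Unique reads per library ran from 4003792 in a dark-reared SCN library to 11169087 in a dark-reared visual cortex library, and allele reads from 548644 in a dark-reared retina library to 3331266 in a dark-reared motor cortex library. The labels name no animal or pool. The libraries of a group come from different crosses, apart from the 2 dark-reared F1r libraries of visual cortex, which may be repeats of 1 sample. Within every tissue the 2 rearings carry different date labels, so rearing and date cannot be told apart.

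The mitochondrial ribosomal RNA mt-Rnr2 took 62.2% and 68.0% of unique reads in the normally reared visual cortex libraries, 59.995% and 63.3% in the dark-reared visual cortex F1r libraries and 57.2% in the normally reared motor cortex F1i library. In the other 12 libraries its share ran from 0.259% to 10.1%. Log2 FPKM of libraries of 1 group correlated across genes at 0.883 to 0.964, where genes are not independent replicates.

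In visual cortex, dark rearing was compared with normal rearing to ask which genes follow visual experience. Metallothionein Mt3 (chromosome 8, 94152607 to 94154148), a zinc-binding protein of neurons and astrocytes, stood at 540.0 ± 49.5 FPKM (SD, n = 3) in the dark against 229 ± 23.4 (n = 2), a log2 change of 1.22 ± 0.18 (SE, adjusted p = 0.0319). Spink8 (chromosome 9, 109812280 to 109826633), a hippocampal marker, rose from 1.15 ± 1.18 to 8.14 ± 1.87 FPKM, a log2 change of 2.13 ± 0.30 (adjusted p = 0.0265). In unique reads neither passed (adjusted p = 0.0717 for Mt3 and 0.0999 for Spink8). The amount of hippocampal tissue in the libraries was not measured. Uqcr11 of complex III went from 219.9 ± 34.5 to 478 ± 72.7 FPKM, with a log2 change of 1.07. Ndufv3 of complex I went from 58.4 ± 2.74 to 163 ± 30.0, with a log2 change of 1.41, but did not pass in unique reads (0.79, adjusted p = 0.291).

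Of 15706 genes tested, 27 were higher and 11 lower in the dark (1850 at an unadjusted p under 0.05). All 38 had groups that did not overlap. Chance gives this in 20% of unselected genes, but these genes were chosen by p in the same libraries, so it adds no support. The same holds for the chance shares of the comparisons below. Others that rose were Nme2, a nucleoside diphosphate kinase (log2 1.40), Bloc1s1, a subunit of a lysosome biogenesis complex (1.33), Smim26 (1.28), the histone Hist2h2ab (1.17), the ribosomal proteins Rps13 (1.17) and Rpl18 (0.82) and the signalosome subunit Cops9 (1.02). Those that fell were the death receptor Tnfrsf25 by 1.42, the tubulin Tuba1c by 1.21 and Rasgef1c by 0.84 on the log2 scale, and each had fewer than 10 unique reads in every library. By edgeR on unique reads, 6 of the 38 passed, and Tuba1c, Rasgef1c and Rpl18 had the opposite sign.

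None of the 26 tested early activity genes, the transcription factors and signalling genes that follow neuronal firing within minutes, passed in visual cortex (0 adjusted over the list alone), and the list as a whole did not differ (median log2 -0.17, camera adjusted p = 0.725). Fos had a log2 value of -0.12 ± 0.55, Egr1 of -0.94 ± 0.50, Npas4 of 0.37 ± 0.37 and Nr4a1 of -0.46 ± 0.50. The 29 later activity genes were shifted downwards as a list (median -0.25, adjusted p = 0.0108), with Bdnf, a growth factor for inhibitory synapse maturation, at -0.78 ± 0.22 and the prostaglandin synthase Ptgs2 at -0.92 ± 0.25, and 0 members passing. The adjusted p of the later list was 0.705 with an estimated correlation.

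The 27 ribosomal protein genes all had positive values in the dark-reared visual cortex (median 0.47, camera adjusted p = 1.12e-15, but adjusted p = 0.382 with an estimated correlation). Of these, 1 rose over all genes and 10 adjusted over the list alone. The 27 nuclear oxidative phosphorylation genes moved the same way (median 0.35, 5.29e-09, but adjusted p = 0.705 with an estimated correlation), with 0 rising over all genes and 8 adjusted over the list alone, among them Cox5b at 0.99 ± 0.21 and Ndufb3 at 1.14 ± 0.26. All 20 myelin genes were positive (median 0.65, 1.37e-06, but adjusted p = 0.726 with an estimated correlation), with 0 past the threshold and Opalin at 1.22 ± 0.31. Of 17 microglia genes 14 were positive (median 0.21, 0.0108, but adjusted p = 0.705 with an estimated correlation). The 20 clock genes were shifted downwards (median -0.33, adjusted p = 0.00336, but 0.726 as an adjusted p with an estimated correlation), with 0 past the threshold, Nr1d1 at -1.10 ± 0.44 and Per1 at -0.88 ± 0.39. Of 14 striatal and hippocampal genes only Spink8 passed, and 2 rose adjusted over the list alone. The other 19 lists, cell types of retina and brain among them, did not pass in visual cortex, with 1 bipolar gene higher adjusted over the list alone; for lens genes (median -0.10, mean -0.05) and amacrine genes (median 0.01, mean -0.02) the test pointed up.

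The visual cortex count fell to 4, with 0 higher and 4 lower, with FPKM as deposited, to 6 with the 2 dark-reared F1r libraries averaged, which share a sequencing and a date label, to 3 with a block for the date label and to 0 with the visual cortex libraries alone. Without normally reared replicate 2 or dark-reared replicate 3 it was 3 in each case.

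In motor cortex, a region outside the visual pathway, nearly all changes were decreases. Rgs9, a regulator of G protein signalling in striatal neurons and photoreceptors (chromosome 11, 109225355 to 109298129), stood at 13.3 ± 7.22 FPKM (SD, n = 2) after normal rearing and 2.56 ± 0.649 in the dark, a log2 change of -1.92 ± 0.24 (adjusted p = 0.00318). The replication-dependent histones Hist1h2ad, Hist1h2al and Hist1h4m fell by 2.60 ± 0.20, 1.95 ± 0.19 and 1.91 ± 0.22 on the log2 scale, Hist1h4m from 51.0 ± 2.10 to 12.9 ± 1.74 FPKM. In unique reads the values were -1.30, -0.35 and -0.07, none past the threshold, and Hist1h4m had 145 and 290.0 reads after normal rearing and 340.0 and 301 in the dark. The proton pump subunit Atp6v1h was the named gene that rose, from 54.4 ± 1.62 to 105 ± 13.6 FPKM (log2 0.93 ± 0.16).

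In all, 4 genes were higher and 89 lower in dark-reared motor cortex (1157 at an unadjusted p under 0.05). All 93 had groups that did not overlap, which chance gives in 33.3% of unselected genes. The rest of the named genes were Rps3a2 (log2 -1.78), Sap18b (-1.76), Tuba1c (-1.29) and Tspan9 (-0.82). Of the 89 lower genes 72 had fewer than 10 unique reads in every library, Sap18b with 0 and Rps3a2 with at most 4, and edgeR on unique reads called 0 genes in motor cortex. With FPKM as deposited the median log2 value of all genes was 0.13. The count was 38 with the stricter filter and 226 without the dark-reared F1i library of motor cortex.

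Striatal and hippocampal genes were shifted downwards in dark-reared motor cortex (14 genes, median -1.10, adjusted p = 2.09e-05, but adjusted p = 0.972 with an estimated correlation). Rgs9 was the member that fell, and 7 fell and 1 rose adjusted over the list alone. The adenosine receptor Adora2a stood at -2.03 ± 0.47 and the dopamine receptors Drd1 and Drd2 at -1.24 ± 0.36 and -1.43 ± 0.47, none past the threshold over all genes. In single libraries Adora2a was at 11.6 and 3.88 FPKM after normal rearing and at 1.66 and 0.393 in the dark. The amount of striatal or hippocampal tissue in the libraries was not measured. A difference in it cannot be told apart from a change in expression, here or in the comparisons with visual cortex. Myelin (median -0.68, adjusted p = 0.00140), cortical layer (-0.34, 0.00970), synapse (-0.32, 0.0243) and mitochondrially encoded genes (-1.41, 0.000238) were shifted downwards and oxidative phosphorylation genes upwards (0.19, 0.000238), with 0 members of each past the threshold. With an estimated correlation each of these lists had an adjusted p = 0.972. Of the dark-reared motor cortex libraries only the F1r library uses the newer gene set, in which mt-Co2 and mt-Co3 were far lower in every library. The rod list had 1 member that fell, again Rgs9, and the other 20 lists did not pass, early activity genes included (median -0.03, adjusted p = 0.925).

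The dark effect itself differed between visual and motor cortex for 33 genes, 30 with the higher value in visual cortex and 3 with the lower (1351 at an unadjusted p under 0.05). Named ones were Hist1h2ad, with a difference in log2 change of 2.53 ± 0.27, Rgs9 (2.42 ± 0.33), the ribosomal gene Rps10 (1.27 ± 0.21, but -0.43 in unique reads, at most 14 in a library) and the tetraspanin Tspan9 (1.23 ± 0.20). Tspan9 stood at 11.8 ± 1.96 and 16.1 ± 1.83 FPKM in normal and dark-reared visual cortex and at 21.02 ± 3.51 and 11.4 ± 0.208 in motor cortex. Of the 33, 24 had fewer than 10 unique reads in every library and 0 were also called by edgeR on unique reads, which called 11 others. The count was 0 with a pseudocount of 0.1 and 170 without the dark-reared F1i library of motor cortex.

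In the retina, dark rearing was compared with normal rearing at the first stage of the visual pathway. Optc, a vitreous proteoglycan (chromosome 1, 133897199 to 133907999) with at most 6 unique reads in a library, rose from 0.761 ± 0.522 to 9.80 ± 3.71 FPKM (SD, n = 2; log2 2.61 ± 0.26, adjusted p = 0.00102), and Col4a1, a basement membrane collagen (chromosome 8, 11198423 to 11312826), rose from 2.35 ± 0.654 to 10.4 ± 2.45 (1.77 ± 0.21). Of 15 retinal pigment epithelium genes 3 fell: Rpe65, the retinoid isomerase, from 34.6 ± 12.4 to 10.1 ± 7.89 FPKM (log2 -1.85 ± 0.37), the retinal G protein receptor Rgr from 65.9 ± 21.5 to 24.8 ± 7.65 (-1.37 ± 0.20) and Lrat, which esterifies retinol, from 5.35 ± 2.14 to 1.81 ± 0.300 (-1.14 ± 0.19). None of the 3 passed in unique reads (adjusted p = 0.815, 0.0850 and 0.198). The amount of pigment epithelium in the libraries was not measured, so a difference in it cannot be told apart from lower expression. Among rod genes Cngb1, a subunit of the cyclic nucleotide-gated channel, rose from 58.2 ± 13.3 to 171 ± 17.6 FPKM (1.55 ± 0.17). Rpgrip1, a protein of the photoreceptor cilium, rose from 36.7 ± 16.1 to 119 ± 17.5 (1.73 ± 0.30). The models of both genes differ between the gene sets, and both dark-reared retina libraries use the newer one; in unique reads Cngb1 did not pass (1.35, adjusted p = 0.0722).

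In all, 74 genes were higher and 95 lower in dark-reared retina (1535 at an unadjusted p under 0.05). All 169 had groups that did not overlap, which chance gives in 33.3% of unselected genes. Col4a1 and Rpgrip1 were among the 16 that edgeR on unique reads called as well, and it called 2 of the 169 in the opposite direction. The rest of the higher named genes were Tnfrsf22 (log2 4.18, but -0.11 in unique reads, at most 1 in a library), Nktr (2.09, but -0.44), the glycolytic enzyme Pgam1 (1.97), the ubiquitin ligase Cop1 (1.90), the phosphatase subunit Ppp2r5a (1.72, but -0.28), the RNA-binding protein Tardbp (1.67) and the water channel Aqp1 (0.86). For Tnfrsf22, Nktr, Cop1, Ppp2r5a and Tardbp the gene models differ between the sets. The potassium channel Kcnj13 fell by 1.87. The mitochondrial transcripts mt-Co3 and mt-Nd3 fell by 9.90 ± 1.90 and 8.84 ± 1.72. In all 5 libraries with the newer gene set, both dark-reared retina libraries among them, mt-Co3 was between 6.85 and 50.5 FPKM, and in the other 12 it was at least 10542.

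Several genes were listed at 0 in both dark-reared retina libraries and in all libraries with the newer gene set. Srsf1, a splicing factor, was at 153.5 and 143.9 FPKM in the normally reared retina and Cabp4, a calcium-binding protein of the photoreceptor synapse, at 65.8 and 72.1. Pitpnm1 was at 149.7 and 96.5, Mat2a at 99.9 and 83.0, and Cdk2ap2, Rnf181, Coro1b and Vezf1 were listed at 0 in the same way. Each of the 8 has a second copy on an alternate contig of the newer gene set. In unique reads, Srsf1 had a log2 value of 0.11 in the dark retina and Cabp4 of -0.38, neither past the threshold.

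The retinal pigment epithelium list had 3 falling genes adjusted over the list alone as well, with a median of -0.18 and 6 positive values (list adjusted p = 0.0236, but adjusted p = 0.933 with an estimated correlation). The 14 endothelial and pericyte genes were shifted upwards (median 0.19, adjusted p = 0.0236, but adjusted p = 0.933 with an estimated correlation), with 0 past the threshold and 1 adjusted over the list alone, the adhesion molecule Pecam1 standing at 0.87 ± 0.20. Of 13 mitochondrially encoded genes 2 fell, and 7 fell and 1 rose adjusted over the list alone (median -1.52, adjusted p = 5.10e-07, but adjusted p = 0.743 with an estimated correlation). In the choroid plexus list Aqp1 rose and Kcnj13 fell, and in the rod list of 22 Cngb1 rose, with 3 others falling adjusted over the list alone (list adjusted p = 0.245). Early activity genes (median 0.06, adjusted p = 0.820) and the remaining lists did not pass, with 1 synapse gene higher adjusted over the list alone. The lens crystallin Cryaa, a gene of another eye tissue, was at 33.3 and 932 FPKM in the normally reared retina libraries and at 468 and 573 in the dark-reared ones.

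The retina count was 0 with the retina libraries alone, 57 with FPKM as deposited (14 higher and 43 lower) and with genes of 1 model in both sets, and 855 without the dark-reared F1r library of retina.

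In the SCN few genes passed. Dlk1 (chromosome 12, 109452823 to 109463336), a paternally expressed regulator of precursor cells, was at 25.9 and 12.8 FPKM after normal rearing and listed at 0 in both dark-reared libraries (adjusted p = 7.65e-06). Its unique reads, at most 28 in a library, gave a log2 value of 0.03. Cuedc1, at 5.02 and 4.78 FPKM after normal rearing, was listed at 0 in both dark-reared SCN libraries and has a second copy in the newer gene set; in unique reads its log2 value was 0.70. In all, 9 genes were higher and 5 lower (952 at an unadjusted p under 0.05), and Dlk1 and Cuedc1 were the named coding genes among them. All 14 had groups that did not overlap, which chance gives in 33.3% of unselected genes. By edgeR on unique reads 412 genes passed, 1 of them shared, and the count was 0 with the SCN libraries alone.

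Peptide genes of neighbouring hypothalamic nuclei were shifted downwards in the dark-reared SCN (16 genes, median -0.53, adjusted p = 0.00236, but adjusted p = 0.741 with an estimated correlation), with 0 past the threshold, neurotensin Nts at -1.55 ± 0.67 and galanin Gal at -1.01 ± 0.50. Rod genes were shifted upwards (22 genes, median 0.23, adjusted p = 0.000499), as were endothelial genes (median 0.23, 0.0162), and inhibitory neuron genes downwards (25 genes, median -0.20, 0.0202). With an estimated correlation these lists had an adjusted p = 0.968. No member of these lists passed, and Gnat1, the rod transducin, stood at 1.16 ± 0.54. Its level in SCN was low, with an SD above the mean over the SCN libraries of both rearings. Retina and SCN libraries of each cross and rearing share a sequencing label, and the source of rod reads in SCN was not tested. Both dark-reared SCN libraries use the newer gene set, in which mt-Co3 was at most at 50.5 FPKM. The 13 mitochondrially encoded genes were shifted downwards as a list (median -1.59, adjusted p = 1.43e-11, but adjusted p = 0.233 with an estimated correlation), with 0 falling over all genes and 10 adjusted over the list alone. None of the 20 clock genes passed: Per1 stood at -0.24 ± 0.43, Per2 at -0.11 ± 0.34 and Arntl at 0.11 ± 0.16, and the SCN peptides Vip and Avp at 0.57 ± 0.52 and -0.31 ± 0.33. Early and later activity genes (adjusted p = 0.925 for both) and the other lists did not pass, with 1 choroid plexus gene lower adjusted over the list alone.

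The dark effect differed between retina and SCN for 31 genes, 9 with the higher value in retina and 22 with the lower (605 at an unadjusted p under 0.05). Optc (difference 2.70 ± 0.37) and Cngb1 (1.61 ± 0.24) were higher, and Muc19, a secreted mucin, was lower (-1.87 ± 0.19), as was Wdr89 (-1.04 ± 0.16). Dlk1, Cabp4, Gpr152 and Cabp2 also passed (adjusted p = 0.000322, 2.43e-08, 5.96e-07 and 2.28e-05), each with a group listed at 0. All dark-reared libraries of both tissues use the newer gene set, so these zeros cannot be told apart from a change of gene set. Of the 31, 20 had fewer than 10 unique reads in every library, and edgeR on unique reads called 0. With FPKM as deposited the median of all genes was -0.19, and the count was 183 without the dark-reared F1r library of retina.

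Averaged over the 4 tissues, 110 genes were higher and 182 lower in the dark (1885 at an unadjusted p under 0.05). Sh3bp1, a GTPase activator, and Tonsl, a replication fork protein, rose most (log2 2.82 ± 0.56 and 2.65 ± 0.50). Sh3bp1 stood between 22.7 and 62.9 FPKM in the 5 libraries with the newer gene set and at most at 1.82 in the other 12. Unique reads followed the gene set too: Tonsl had 160.0 to 1567 in the 5 libraries and at most 18 in the others, Tmco1 4 to 12 and at most 2, and Arhgef40 3 to 87 and 0. The rest of the named higher genes were the kinase Alpk2 (2.41), Tnfrsf22 (1.77), the calcium channel Tmco1 (1.12), Nktr (1.04, but -0.43 in unique reads), Cop1 (0.94), Arhgef40 (0.94), the splicing factor Prpf19 (0.94), Cebpzos (0.93), Spink8 (0.79), Ndufs1 of complex I (0.43) and Cngb1 (0.41). The mitochondrial transcripts mt-Atp6 (-5.96 ± 0.95), mt-Co2 (-5.84), mt-Co3 (-5.74), mt-Nd3 (-4.16) and mt-Nd4 (-1.83) were lower. Srsf1, Ppp1ca, Mat2a, Pitpnm1, Ranbp1 and Gstp1 passed as lower too, and each was listed at 0 in the libraries with the newer set and has a second copy there. By edgeR on unique reads Ppp1ca was higher in the dark by 1.07 (adjusted p = 0.00836), 43 of the 292 passed in the same direction and 23 in the opposite one. With genes of 1 model in both sets the count was 80, and 112 without the normally reared F1r library of visual cortex.

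Across tissues, 5 of 13 mitochondrially encoded genes fell (10 adjusted over the list alone; median -1.24, adjusted p = 1.05e-11, but adjusted p = 0.227 with an estimated correlation). Unique reads of mt-Co2 numbered at most 1 in the 5 libraries with the newer gene set and at least 1461 in the other 12, dark-reared ones included. Ribosomal protein genes (25 of 27 positive, median 0.17, adjusted p = 1.86e-05) and oxidative phosphorylation genes (25 of 27 positive, median 0.10, 0.00137) were shifted upwards, the latter with Ndufs1 past the threshold. The Ndufs1 model differs between the gene sets, and its unique reads were 7 to 52 in the newer-set libraries and at most 9 in the others (adjusted p = 0.528). Endothelial genes were shifted upwards (median 0.11, 0.0221), and synapse (median -0.15, 0.0284) and later activity genes (median -0.12, 0.0428) downwards, with 0 members passing. Each of the last 5 lists had an adjusted p = 0.848 with an estimated correlation. Cngb1 and Spink8 were the passing members of the rod and the striatal and hippocampal lists, and the remaining lists did not pass, with 1 choroid plexus gene lower adjusted over the list alone.

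Visual cortex was compared with motor cortex, over both rearings, to set regional differences beside the effect of rearing. Only the dark-reared F1i libraries of both regions share a date label, so region and date are largely confounded. Chance was not excluded for the count of this comparison (12 of 100 splits gave at least the 6 genes of the real split in an additive model). Early activity genes were higher in the visual cortex libraries. Fos (chromosome 12, 85473890 to 85477273) stood at 37.9 ± 17.7 FPKM (SD, n = 5) against 6.85 ± 4.83 (n = 4), a log2 difference of 2.43 ± 0.41 (SE, adjusted p = 0.0111). Egr1 (chromosome 18, 34859823 to 34864984) stood at 57.9 ± 34.3 against 14.1 ± 11.7, a difference of 2.25 ± 0.37 (adjusted p = 0.00991), and Npas4, which organises inhibitory synapses after firing, at 8.83 ± 3.93 against 1.17 ± 0.449 (2.09 ± 0.27). Of the 26 genes of the list 13 were higher over all genes and 20 adjusted over the list alone, with a median of 1.13 and 25 positive values. Fos was at 37.9 ± 8.61 in normally reared and 38 ± 24 in dark-reared visual cortex.

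**Figure D1:**
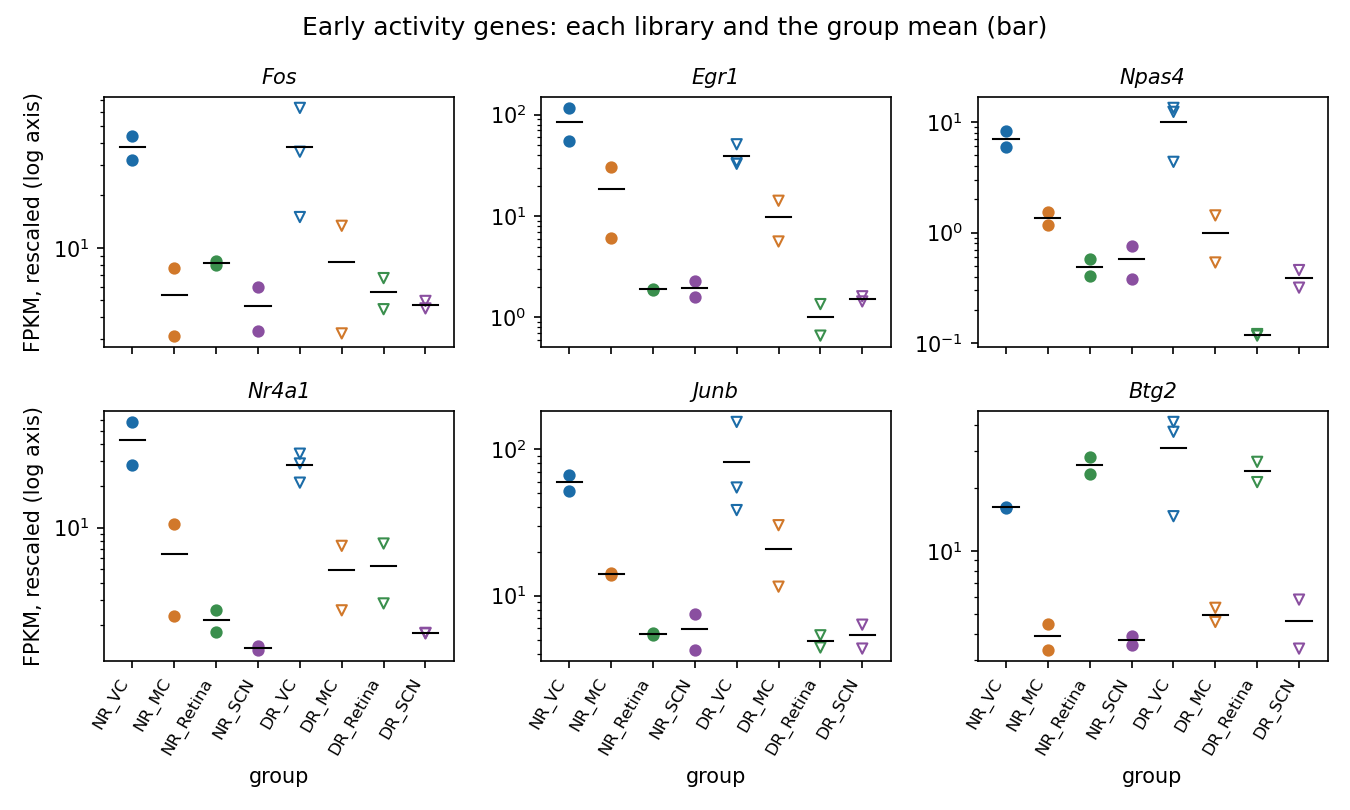
Rescaled FPKM of Fos, Egr1, Npas4, Nr4a1, Junb and Btg2 on a log axis, with 1 point per library (triangles, dark-reared) and a bar at the mean of each of the 8 groups. Fos averaged 37.9 FPKM over the 5 visual cortex libraries and 6.85 over the 4 motor cortex libraries.

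The other activity genes named were Nr4a1 (log2 2.61), Btg2 (2.06), Ccn1 (1.97), Junb (1.93), Dusp1 (1.86) and Nr4a2 (1.49, but -0.21 in unique reads). The layer genes higher in visual cortex were Fezf2 (0.89) and Ntsr1 (0.93), markers of deep-layer projection neurons, and Etv1 (0.75) of layer 5, and the synapse genes named were the glutamate transporter Slc17a6 (0.97) and the receptor Grm5 (0.29). Other genes higher in visual cortex were Tshz2 (2.44), Tenm2 (1.89), C1ql2 (1.86), the peptide gene Grp (1.36), the kainate receptor Grik1 (0.92), Calb2 of an interneuron class (0.76), Kl (0.54) and the clock gene Nr1d2 (0.45). Lower in visual cortex were the sodium channel subunit Scn4b (log2 -2.08 ± 0.32) at 3.82 ± 0.756 FPKM against 21.3 ± 11.8, and proenkephalin Penk (-1.61 ± 0.32) at 8.56 ± 1.95 against 34.4 ± 24.9, which did not pass in unique reads (adjusted p = 0.0778). Tnnc1 (-1.57), Medag (-1.53; adjusted p = 0.102 in unique reads), Gng13 (-1.51), Bok (-1.38), Ccnb1 (-1.34, at most 1 unique read), Tesc (-1.29), Pappa2 (-1.18), Myl4 (-1.16) and Rxrg (-1.11, but -0.03 in unique reads, at most 1 in a library) were lower too, as were the astrocyte genes S100b (-0.78), Gjb6 (-0.72) and Acsbg1 (-0.67).

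In all, 229 genes were higher and 422 lower in visual cortex (3435 at an unadjusted p under 0.05), 316 of the 651 with tissues that did not overlap, against a chance share of 1.59%. Of 27 ribosomal protein genes 3 were lower (11 adjusted over the list alone), Rpl27 by 0.44 among them, and of 27 oxidative phosphorylation genes 6 (18 adjusted over the list alone). Of 13 astrocyte genes 3 were lower (4 lower and 1 higher adjusted over the list alone), of 21 layer genes 3 were higher (3 adjusted over the list alone) and of 14 striatal and hippocampal genes 1 was higher and 3 lower (4 and 7 adjusted over the list alone). By edgeR on unique reads 130 of the 651 passed, Fos, Egr1, Npas4, Nr4a1 and Scn4b among them. The count was 150 with FPKM as deposited (23 higher and 127 lower), 138 without the dark-reared F1r library of motor cortex and 1712 without the dark-reared F1i library of visual cortex.

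Retina and SCN were compared as the tissues of the light input and of the clock it entrains. Rod transducin, Gnat1 (chromosome 9, 107674477 to 107679592), stood at 2544 ± 311 FPKM (SD, n = 4) in retina and 1.40 ± 2.56 in SCN (log2 10.52 ± 0.38, adjusted p = 3.38e-09). The hypothalamic peptides went the other way: oxytocin, Oxt, was at 526 ± 271 FPKM in SCN and 1.26 ± 1.81 in retina (log2 -7.94 ± 0.51, adjusted p = 2.49e-07) and vasopressin, Avp, at 288 ± 95.9 and 1.63 ± 1.01 (-6.82 ± 0.23). The myelin gene Mbp was higher in the SCN libraries, at 1259.8 ± 661 against 4.60 ± 1.33 in retina.

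Of the 22 rod genes all 22 were higher in retina, with Pdc (log2 10.85), Gngt1 (10.82), Prph2 (10.01), Pde6g (9.39), Guca1a (9.17), Sag (8.93) and Pde6b (8.77) among the highest, together with the microtubule protein Rp1 (8.90). So were 12 of 14 cone genes (Opn1sw at 7.56; 2 lower), 15 of 15 bipolar cell genes, 11 of 17 ganglion cell genes (Pou4f1 at 3.42; 3 lower), 8 of 16 amacrine and horizontal cell genes (Pax6 at 5.21; 6 lower, median 0.29), 8 of 14 Muller glia genes (Rlbp1 at 5.43; 4 lower), 11 of 15 pigment epithelium genes (Rgr at 5.32; 1 lower) and 16 of 19 lens genes (Cryaa at 7.70). Adjusted over the list alone the counts were the same, apart from 17 higher lens and 5 lower Muller glia genes. Of the 20 clock genes 15 were higher in retina and 1 lower (15 and 1 adjusted over the list alone), with Arntl at 1.87 and Dbp at 1.29. Lower in retina were 18 of 20 myelin genes (1 higher), 11 of 13 astrocyte genes (Gfap at -4.55), 17 of 17 microglia genes (C1qa at -2.41), 20 of 25 inhibitory neuron genes (Gad2 at -3.24; 4 higher), 19 of 27 synapse genes (3 higher), 12 of 16 hypothalamic peptide genes (Sst at -4.15, Hcrt at -3.14; 2 higher) and 12 of 19 SCN neuron genes (Penk at -2.72; 3 higher), as many adjusted over the list alone. The glutamate transporter Slc17a7 was higher in retina (7.33), as were the SCN list's Vipr2 (1.84) and the pericyte list's Vtn (5.28). Other genes lower in retina were Mobp (-7.64), Cldn11 (-6.54), Itih3 (-5.98), Trh (-5.85), Mal (-5.72) and Gpr37l1 (-5.64).

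In all, 4441 genes were higher and 5000.0 lower in retina (10008 at an unadjusted p under 0.05), 7947 with tissues that did not overlap, against a chance share of 2.86%. With FPKM as deposited the median of all genes was -0.53, with 1685 genes then higher and 7211 lower. By edgeR on unique reads 6012 genes passed, 5513 of them shared with the same sign and 30 with the opposite one.

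The crosses were compared to set maternal genome and strain of the X chromosome beside rearing. In F1r libraries, with a B6 mother, 6 genes were higher and 12 lower (877 at an unadjusted p under 0.05), 9 of the 18 without overlap between the crosses against a chance share of 0.00823%. Of the 18, 8 are X-linked and 1 is mitochondrial. Higher in F1r were Tmsb15b1, a thymosin gene (log2 2.69), mt-Nd1 (2.32), the X-linked noncoding RNA Firre (1.23), 1810030O07Rik (0.95), Apoo, a mitochondrial membrane protein (0.66), and Bex4 (0.57). Lower were Tmsb15b2 (-1.50), Slc25a53 (-0.98), Zfp280c (-0.72), the pseudogene Apoo-ps (-2.03) and 8 predicted genes. In the mitochondrial list mt-Nd1 rose (6 adjusted over the list alone), 1 stress gene fell adjusted over the list alone, and no other list had a passing member. By edgeR on unique reads 11 of the 18 passed. Bias of the reads towards the reference strain was not separated from a difference in expression. With FPKM as deposited the median of all genes was 0.12.

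Parental origin of reads was tested to find imprinted genes, with both crosses separating parent from strain. Averaged over tissues, 20 of 6602 autosomal genes passed, 7 with more maternal and 13 with more paternal reads (263 at an unadjusted p under 0.05). The count was 31 without chromosome 19 and 51 without the normally reared F1r libraries of retina and SCN. Of the 54 genes of a list of known imprinted genes 17 had enough reads in every tissue, 15 passed over all genes and 17 adjusted over the list alone, and 14 were in the known direction. Peg3 (chromosome 7, 6703892 to 6730421), a paternally expressed zinc finger gene, had 1.34% maternal reads of 60655 (log2 -8.83 ± 0.43, SE, adjusted p = 2.20e-05, n = 17 libraries by edgeR), and 665 of its 813 maternal reads come from the normally reared F1r library of SCN. Meg3 (chromosome 12, 109541001 to 109571726), a maternally expressed noncoding RNA, had 99.5% of 36216 (8.37 ± 0.33).

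Other paternally read genes were Ndn (log2 -8.38), Usp29 (-8.65), Zrsr1 (-7.05), Impact (-6.35; chromosome 18, 12972252 to 12992948), Rasgrf1, a Ras activator in neurons (-6.33; chromosome 9, 89909775 to 90026976), Plagl1 (-5.76), Mcts2 (-4.70) and Mest (-2.29, 16.8% maternal). Maternal reads prevailed at Ube3a, the ubiquitin ligase of the Angelman region (1.97, 80.9%; chromosome 7, 59228752 to 59306727), Ago2 (1.42, 73.1%), H13 (1.13, 70.1%) and Igf2r (0.40, 57.2%). Trappc9, listed as maternal, gave -3.47 (chromosome 15, 72589621 to 73061204), with maternal shares of 62.3 ± 11.7% in retina and 1.92 ± 3.85% in visual cortex (SD, n = 4 each); the paternally expressed Peg13 lies within it. Rtl1, listed as paternal and overlapped by a maternally expressed antisense transcript, had 79.3% maternal reads and did not pass (adjusted p = 0.0706), nor did Commd1 (0.95, adjusted p = 0.193). Outside the list, Copg2, next to Mest (1.51 ± 0.05; chromosome 6, 30747554 to 30896794), and Herc3 (0.55 ± 0.05) had a fitted excess of maternal reads. At Herc3 the maternal share outside SCN was 25.8% to 49.2% in F1i and 62.6% to 70.4% in F1r libraries. Only in SCN, at 66.3% to 80.7%, did maternal reads of Herc3 prevail in both crosses. Begain, in the region of Dlk1 and Meg3 (-0.83 ± 0.05; chromosome 12, 109032187 to 109068217), Tex261 (-1.01 ± 0.08) and Stambp (-0.76 ± 0.09) had a fitted excess of paternal reads. In visual cortex the maternal share was 44.7% to 61.7% for Tex261 and 40.7% to 57.1% for Stambp. For Tex261 it was 43.0% to 50% in the F1i libraries of all tissues. Its low shares, 13.3% to 17.1%, were those of the F1r libraries of motor cortex, retina and SCN, so they were seen in 1 cross only.

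**Figure D2:**
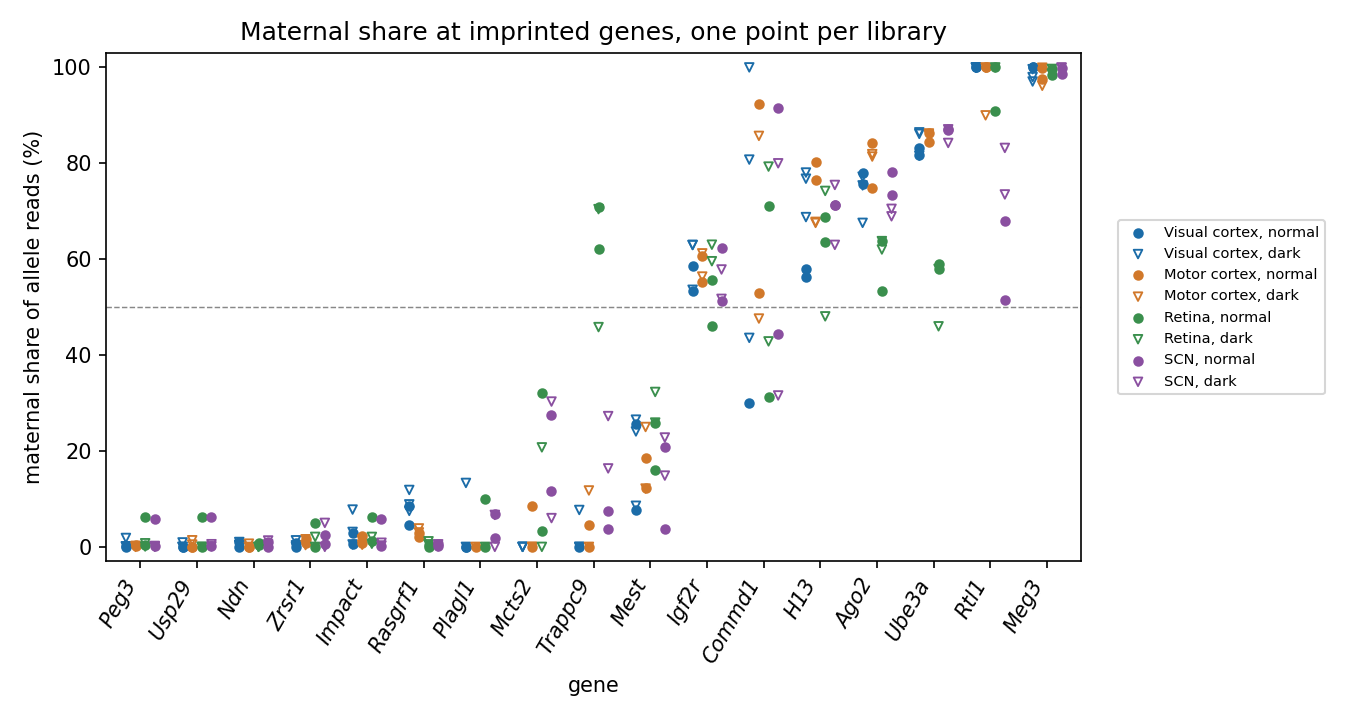
Maternal share of allele reads, in percent, at the 17 tested genes of the imprinted list, with 1 point per library that had at least 10 reads (filled circles, normal rearing; open triangles, dark rearing; colours, tissues). Peg3 lies between 0% and 6.29% and retina points of Ube3a lie lower than those of the other tissues.

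Parental reads were also tested in each tissue. In visual cortex 11 genes passed, 10 of them in the imprinted list (16 adjusted over the list alone), in motor cortex 14 with 12 (17), in retina 7 with 6 (16) and in SCN 16 with 10 (17). At an unadjusted p under 0.05 the counts were 212, 173, 341 and 146. With an extra B6 effect for the newer gene set 17 genes passed in visual cortex, 20 in retina and 35 in SCN, and 14 between tissues. Without single libraries the count fell as low as 3 in visual cortex, 7 in motor cortex and 4 in retina, and rose to 14 in retina. The parental effect differed between tissues for 5 genes (162 at an unadjusted p under 0.05; 3 without the normally reared F1i or the dark-reared F1r library of SCN), 2 of them listed (6 adjusted over the list alone). The share of maternal reads at Ube3a was 83.8 ± 2.37% in visual cortex (SD, n = 5), 85.7 ± 0.808% in motor cortex, 86.3 ± 1.40% in SCN and 55.2 ± 6.2% in retina (n = 4 each; adjusted p of the difference 0.00271, edgeR). Rasgrf1 had 8.25 ± 2.63% maternal reads in visual cortex, 2.94 ± 0.761% in motor cortex, 0.495 ± 0.495% in retina and 0.319 ± 0.251% in SCN (adjusted p = 0.000554). Copg2 was most maternal in SCN, at 87.4 ± 1.99%, and least in retina, at 58.0 ± 6.81% (0.00459). Herc3 was at 73.6 ± 6.53% in SCN and 48.2 ± 19.7% in retina (0.0259), and Begain at 14.8 ± 3.14% in SCN and 44.3 ± 4.35% in visual cortex (0.00113). In SCN alone Klhdc10 (log2 0.83 ± 0.09) and Ppp1r9a (0.75 ± 0.09) had more maternal reads; their difference from the other tissues did not pass.

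No gene passed the test for a parental effect that differs by rearing. For the average over tissues this test called 24 and 27 of 50 log2 changes of -1 and 1 planted in simulated data, and single tissues were not simulated. With edgeR, 0 genes passed for the average over tissues (236 at an unadjusted p under 0.05) and 0 in visual cortex, motor cortex, retina and SCN (191, 121, 288 and 156), with 0 of the 17 imprinted genes adjusted over the list alone. DESeq2 called 0 for the average, visual cortex, retina and SCN and 1 in motor cortex. In visual cortex Ube3a had 82.4% maternal reads after normal and 84.1% after dark rearing, Meg3 100% and 98.5%, Impact 1.91% and 2.88%, and Rasgrf1 6.64% and 9.39%. The other-parent share of Peg3 was 6.29% (95% Wilson interval 4.99% to 7.90%) and 5.74% (5.3% to 6.2%) in the normally reared F1r libraries of retina and SCN, which share a sequencing label. There that share was 6.24% and 5.85% for Impact and 6.15% and 6.32% for Usp29, but 0.395% and 0.0482% for Ndn and 0.287% and 0.0788% for Meg3. Without that retina library the retina count was 14, and without both libraries it was 15 in retina, 1 in SCN and 2 on average. With an extra B6 effect for the newer gene set 6 genes passed in visual cortex.

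Strain of origin was tested in the same fit. The fitted effect favoured B6 at 2428 genes and CAST at 786 (3619 at an unadjusted p under 0.05). Bias of the reads towards the reference strain was not separated from this. The smallest adjusted p values belonged to Ppp2r2c, a phosphatase subunit (log2 1.73 ± 0.03, adjusted p = 1.58e-08), Rpl8 (2.09 ± 0.04), Rpn1 (2.54), Serf2 (-3.14 ± 0.07), the noncoding Rprl2 (-8.79), Mzt1 (2.17), the zinc transporter Slc30a4 (-1.94), Scg5 (-1.15), Rps15 (3.78) and the elongation factor Eef2 (-0.83). Of the imprinted list 7 passed (6 adjusted over the list alone), all with a positive B6 effect: Commd1 (1.51), Peg3 (1.42), Meg3 (1.37), Impact (1.25), Mest (0.67), Igf2r (0.21) and Ago2 (0.17). At Peg3, Meg3 and Impact nearly all reads came from the expressed parent, so this effect does not mean more B6 reads in sum. With a minimum of 50 reads the count was 1742.

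Chromosome 19 stood apart in strain. In the 5 libraries with the newer gene set, all dark-reared, B6 reads made up 89.1% to 91.4% of its allele reads, and in the other 12 libraries 52.1% to 54.7%. The other autosomes ran from 33.8% to 59.2%. Of 307 genes of the chromosome with at least 100 reads in these 5 libraries 195 had more than 90% B6 reads.

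**Figure D3:**
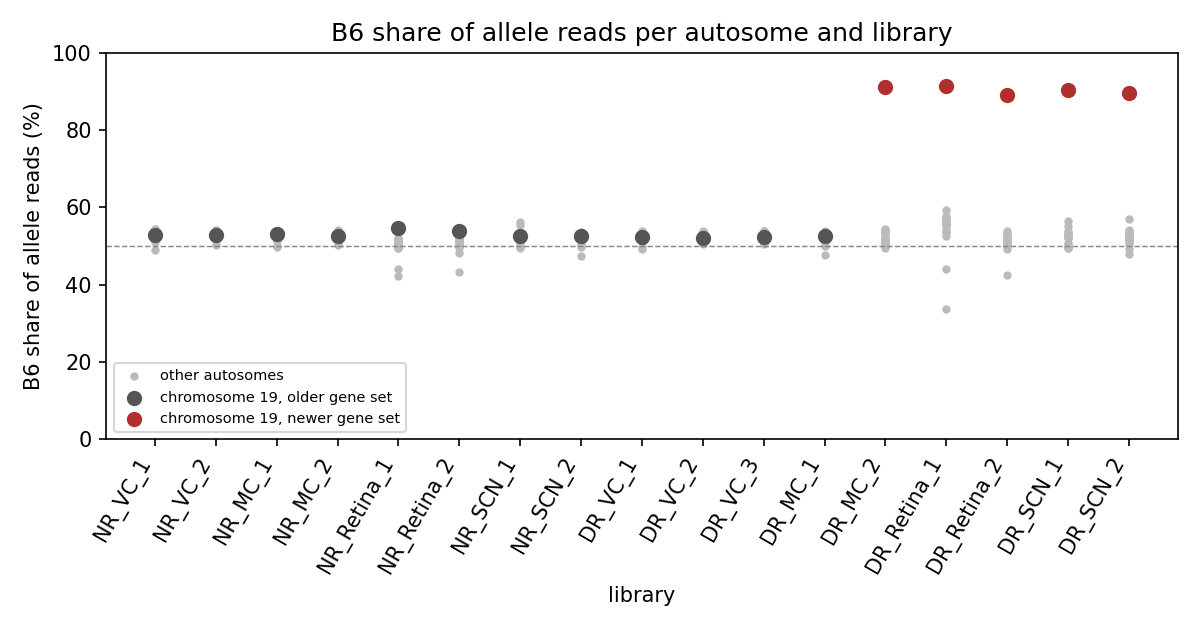
B6 share of allele reads, in percent, for each autosome in each of the 17 libraries (grey, other autosomes; dark grey and red, chromosome 19 with the older and the newer gene set). Chromosome 19 lies at 89.1% to 91.4% in the 5 libraries with the newer set and at 52.1% to 54.7% in the other 12.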

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

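Apart from the test for missing CAST reads and the splits of the allele comparisons, the tests in this part were chosen after the result was seen. No group holds 4 libraries, so single libraries were not tested for standing apart within their group.

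The effect of dark rearing differed between visual and motor cortex for 33 genes by the interaction term. Among named genes the difference in log2 change was 2.53 for Hist1h2ad, 2.42 for Rgs9, 1.27 for Rps10 and 1.23 for Tspan9. It differed between retina and SCN for 31 genes. There the difference was 2.70 for Optc, 1.61 for Cngb1, -1.87 for Muc19 and -1.04 for Wdr89. For Dlk1 (adjusted p = 0.000322), Cabp4 (2.43e-08), Gpr152 (5.96e-07) and Cabp2 (2.28e-05) a group is listed at 0, so no fold is given. All dark-reared retina and SCN libraries use the newer gene set, in which Cabp4 was listed at 0 in every library. A dark effect on these genes cannot be told apart from a change of gene set. By edgeR on unique reads 0 genes passed for the difference between retina and SCN. The parental effect differed between tissues for 5 genes: Ube3a (adjusted p = 0.00271), Rasgrf1 (0.000554), Begain (0.00113), Copg2 (0.00459) and Herc3 (0.0259). For this count the real split gave the most, 5 genes against at most 3 in any other of the 100 splits, 1 of which, the real one, gave as many. Without the normally reared F1i or the dark-reared F1r library of SCN the real count was 3 as well, so chance was not firmly excluded.

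Chromosome 19 had 89.1% to 91.4% B6 reads in the 5 libraries with the newer gene set and 52.1% to 54.7% in the other 12. CAST reads missing from the tables would have lowered the chromosome's share of allele reads, but this was 1.29 times that of the other libraries of the tissue (range 1.12 to 1.41). Dark rearing is argued against by the 4 dark-reared libraries with the older set, the highest of which had 52.6% B6 reads. Both copies from B6 is argued against for genes starting below 32 Mb, of which 105 of 185, 56.8%, had 60% to 90% B6 reads. Above 32 Mb 0% of 122 genes did (median 99.9% B6), so there 2 B6 copies and an assignment of CAST reads to B6 cannot be told apart, as both could give such shares.

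Genes at 0 FPKM in all 5 libraries with the newer gene set and at 1 or more in the other 12 numbered 33. A second copy on an alternate contig was present for 23 of them, 69.7%, against 0.0574% of 10446 other genes, consistent with the value having been lost between 2 copies. For these 23 lower RNA in the dark-reared retina is argued against by their unique reads, with a median log2 change of -0.0269 and quartiles of -0.30 and 0.39. Of the other 10, 6 had 0 unique reads in all 5 libraries, but 100% of these had reads in each of the 4 dark-reared libraries with the older set, which argues against lower RNA in the dark. Why these 10 are listed at 0 stays open.

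The 89 genes lower in dark-reared motor cortex include 72, or 80.9%, with fewer than 10 unique reads in every library, against 18.1% of all tested genes. This is consistent with reads shared between paralogs or pseudogenes. The normally reared motor cortex was the highest of the 8 groups for 85 of them. Normally reared motor cortex lay above normally reared visual cortex by a median of 1.83 (quartiles 1.20 and 2.42) and dark-reared motor above dark-reared visual cortex by 0.02, but the genes were chosen for their level in these libraries, so this cannot tell whether normally reared motor cortex stands apart. Dark rearing cannot be told apart from the date, since 0 date labels hold both rearings of motor cortex.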

How the results depend on the processing

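Beside the settings chosen before the data were examined, 6 kinds were chosen after seeing them: genes of 1 model in both gene sets, genes with a second copy left out, the mt-Rnr2 share as a covariate, both normally reared F1r libraries of retina and SCN left out, chromosome 19 left out, and an extra B6 effect for the newer set. Of 269 counts under whole settings 181 stayed within 1.5 times and 88 moved further. Of 3857 values of named genes under whole settings 3242 kept direction and side of the threshold, 599 kept direction only and 16 reversed. Leaving out 1 library kept 390 of 476 counts within 1.5 times. It kept 4583 of 5423 named values past the threshold, with 840 keeping direction only and 0 reversed. These values were named for passing in the same libraries, so the 0 reversed was largely fixed in advance and adds little support. Leaving out a library against its cross label was not run because at the imprinted genes used for that check none goes against it. Settings with fewer libraries or genes change what is tested; apart from that the cause was not tested. Where a group keeps 1 library, that library is assumed to vary like the other groups.

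With a pseudocount of 0.1 the dark effect counted 44 genes in motor cortex and 9 in SCN, its difference 0 between visual and motor cortex and 19 between retina and SCN. With no filter SCN had 27 and visual against motor cortex 432. With FPKM of at least 1 in 8 libraries the dark effect counted 13 in visual cortex, 38 in motor cortex, 93 in retina, 0 in SCN and 175 on average, with differences of 11 and 0. With FPKM as deposited it counted 4 in visual cortex, 57 in retina and 177 on average, the cortical difference 20, visual against motor cortex 150, and SCN lists 3. Quantile normalisation gave 24 in visual cortex. With the date label as a block the counts were 3 in visual cortex, 100 in retina, 9 in SCN, 93 on average, 19 for the cortical difference and 227 for visual against motor cortex. With the tissues compared alone they were 0 in each tissue, 7 and 13 for the differences and 168 for visual against motor cortex. With both dark-reared visual cortex F1r libraries averaged they were 6 in visual cortex, 112 in retina and 312 for visual against motor cortex. With edgeR on unique reads they were 97 in visual cortex, 0 in motor cortex, 412 in SCN, 580 on average, 11 and 0 for the differences, 272 for visual against motor cortex, 6012 for retina against SCN and 30 for the crosses. Genes of 1 model gave 37 in motor cortex, 57 in retina, 6 in SCN, 80 on average, and 13 and 16 for the differences. The mt-Rnr2 covariate gave 16 in visual cortex, 92 in retina, 120 on average and 164 for visual against motor cortex. Without both normally reared F1r libraries of retina and SCN the counts were 10 in visual cortex, 83 in retina, 98 on average, 16 and 51 for the differences, 305 for visual against motor cortex and 9 for the crosses. With an estimated correlation 0 lists passed in each tissue, on average and in total. No count moved with second copies or the cross left out.

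For parental effects, DESeq2 gave 13 genes in retina, 1 for the rearing difference in motor cortex and 11 between tissues. A minimum of 1 read gave 25 in SCN, and of 50 reads 1742 for B6 against CAST. Without chromosome 19 there were 31 on average, 13 in retina, 26 in SCN, 1 for the rearing difference in SCN and 11 between tissues. The extra B6 effect gave 17 in visual cortex, 20 in retina, 35 in SCN, 6 for the rearing difference in visual cortex and 14 between tissues. Without both normally reared F1r libraries there were 51 on average, 12 in retina, and 2, 15 and 1 for the rearing difference on average, in retina and in SCN. No count moved with limma weights, TMM or X-linked genes.

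Reversed values came from edgeR on unique reads, apart from 1 under TMM, Ago2, B6 versus CAST allele, mean of 4 tissues (-0.00465): in visual cortex Tuba1c (1.93), Rasgef1c (0.89) and Rpl18 (-0.36), in retina Tnfrsf22 (-0.11), Nktr (-0.44), Ppp2r5a (-0.28) and Srsf1 (0.11), in SCN Dlk1 (0.0298) and Cuedc1 (0.70), on average Nktr (-0.43), Ppp1ca (1.07) and Ranbp1 (0.20), in the differences Rps10 (-0.43) and Dlk1 (-2.77), and in visual against motor cortex Nr4a2 (-0.21).

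The share of called genes that were higher moved by over 10 points with FPKM as deposited: from 71.1% to 0% in visual cortex, 43.8% to 24.6% in retina, 35.2% to 15.3% in visual against motor cortex (46.3% with quantile normalisation) and 47.0% to 18.9% in retina against SCN.

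Leaving out 1 library at a time (NR normal, DR dark rearing, VC visual and MC motor cortex), the dark effect counted 3 to 41 genes in visual cortex: 3 without NR_VC_2 or DR_VC_3, 9 without NR_VC_1, 14 without NR_SCN_1 or NR_SCN_2, 16 without DR_MC_1 or DR_MC_2, 18 without NR_Retina_1 or NR_Retina_2, and 23 without DR_SCN_1 or DR_SCN_2. In motor cortex it counted 66 to 226, the latter without DR_MC_1. In retina it counted 58 to 855: 58 without DR_Retina_1, 69 without NR_Retina_1, 91 without NR_Retina_2, 96 without NR_VC_1 or NR_VC_2, 105 without DR_VC_3, 109 without NR_SCN_2, 110.0 without NR_SCN_1, 312 without DR_MC_1 or DR_MC_2 and 855 without DR_Retina_2. In SCN it counted 9 to 192: 9 without NR_VC_1, NR_VC_2 or DR_VC_2, 41 without DR_SCN_1 and 192 without DR_MC_1 or DR_MC_2. On average it counted 112 to 514: 143 and 112 without NR_VC_1 and NR_VC_2, 162 and 148 without NR_MC_1 and NR_MC_2, 171 and 185 without NR_Retina_1 and NR_Retina_2, 158 and 131 without NR_SCN_1 and NR_SCN_2, 187 without DR_VC_3, 440.0 without DR_MC_1, 174 and 514 without DR_Retina_1 and DR_Retina_2, and 168 and 192 without DR_SCN_1 and DR_SCN_2. The cortical difference counted 10 to 170: 18 and 10 without NR_VC_1 and NR_VC_2, 19 without DR_VC_3, 170.0 and 15 without DR_MC_1 and DR_MC_2. The difference between retina and SCN counted 21 to 183, the latter without DR_Retina_2. Visual against motor cortex counted 138 to 1712: 163 and 172 without NR_VC_1 and NR_VC_2, 201 without NR_MC_2, 1712, 287 and 307 without DR_VC_1, DR_VC_2 and DR_VC_3, and 138 without DR_MC_2. Retina against SCN counted 8390.0 to 9636 and the crosses 12 to 23.

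Lists passing without 1 library numbered 6 to 8 in visual cortex, 1 to 6 in motor cortex (1 without NR_MC_1, 3 without DR_MC_2), 1 to 6 in retina (6 without NR_Retina_1, 1 without DR_MC_1 or DR_MC_2), 4 to 9 in SCN (8 without NR_SCN_1 or DR_SCN_1, 9 without DR_SCN_2), 2 to 9 on average (3 without NR_VC_1 or NR_MC_1, 2 without DR_Retina_2) and 18 to 32 in total. Parental effects numbered 17 to 24 on average, 3 to 11 in visual cortex (3 without NR_VC_1, 5 without NR_VC_2 or DR_VC_1), 7 to 14 in motor cortex (7 without any of its 4 libraries), 4 to 14 in retina (4 without any motor cortex library, 14 without NR_Retina_1 or DR_Retina_2) and 13 to 16 in SCN. The rearing difference stayed at 0 on average, in visual cortex and in SCN, reached 1 in motor cortex without NR_MC_2 or DR_MC_2, and in retina 14 without NR_Retina_2 and 6 without DR_Retina_2. B6 against CAST ran from 2694 to 3035, and between tissues 3 to 5 genes passed (3 without NR_SCN_1 or DR_SCN_2). The allele results are limited to the 6602 genes with enough reads in every tissue.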

Other observations

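The tests of the expression splits and of the cross were chosen after the results were seen, and the splits of the allele comparisons before, though more of these splits were drawn after a first set had been seen.

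Genes of the Y chromosome were expressed in all 17 libraries, with a median FPKM of 35.9 for Ddx3y (13.8 to 57.7), 30.4 for Eif2s3y (15.6 to 71.7), 5.59 for Kdm5d (2.82 to 12.3) and 15.6 for Uty (8.15 to 39.9). Xist, the noncoding RNA of the inactive X chromosome, had a median of 0.0222 (0.00382 to 0.248). X-linked allele reads were 97.5% to 99.8% maternal in the 9 F1r libraries but 31.0% to 44.0% maternal in the 8 F1i libraries. With Y-linked genes on and Xist near 0 they would be maternal in both crosses, so the F1i shares go against the label on X, while imprinted autosomal genes of the same libraries go with it; the reason was not tested. Of the 18 genes that differed between the crosses, 50% were X-linked or mitochondrial, against 3.98% of the 15688 others (Fisher's exact test, p = 9.44e-09, odds ratio 24.1). A mitochondrial genome and an X chromosome from different mothers would give such a share. Related genes went in opposite directions: Apoo (0.66) and Tmsb15b1 (2.69) were higher in F1r, and Apoo-ps (-2.03) and Tmsb15b2 (-1.50) lower. Bias of the reads towards the reference strain was not separated from a difference in expression.

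How often other splits of the samples give as many genes was counted with additive models, and for the crosses with a mean for each group. Comparisons between tissues used the libraries of the compared tissues alone. In these fits the dark effect averaged over tissues called 0 genes and visual against motor cortex 6, unlike the 292 and 651 of the group model of all libraries. For the dark effect, with 0 genes in the real split, the count of splits (100 of 100, highest 4) cannot speak to chance. For visual against motor cortex chance was not excluded: 12 of 100 splits gave at least 6 genes, and the highest called 660. That split differs from the real one by the dark-reared F1i visual cortex library alone, which stands with motor cortex in it, shares a date label with the dark-reared F1i motor cortex library and has 7.08% of its unique reads in mt-Rnr2, against 59.995% or more in the other visual cortex libraries. It points to a structure of the samples beside region. For retina against SCN chance was excluded, with 8873 genes against a highest of 81, from the split that separates the rearings and with them the date labels, and 1 of 35 splits giving as many. For the crosses chance was not excluded, with 18 genes and 5 of 100 splits giving as many; the highest of 369 points to a structure of the samples as well.

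In the allele fits the real split gave the most genes for the parental effect, 20 against a highest of 19, with 1 of 100 splits giving as many. The other splits swapped the parents in some libraries only and so kept part of a real effect, so their counts cannot decide on chance. With 1 library left out the real count fell as low as 17. Of the 17 tested genes of the imprinted list, fixed beforehand, 15 passed over all genes. Of these, 14 were in the known direction, which argues against chance for those 14. For the 5 passing genes outside the list chance was not excluded. For B6 against CAST chance was excluded, with 3214 genes against 2396 and 1 of 100. For the parental effect between the rearings, with 0 genes in the real split, the count of splits (100 of 100) cannot speak to chance, and the highest of 242 points to a structure of the samples.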
